A study of Homo sapiens with 6 samples.

How the data were processed

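RNA was extracted with TRIzol, mRNA was isolated with oligo(dT) beads, fragmented, made into cDNA and amplified by PCR, per the labels' protocols. The 6 libraries fall into 3 oeTNFRSF12A and 3 oeControl samples by their titles. The submitters' processing notes name HISAT2 2.2.1, Bowtie2 2.4.5 and RSEM 1.3.1 and the builds GRCh38 and hg38, without giving each its role; the gene annotation, the strand setting of the counting and any filter are not given in the sources used here. The deposited values were taken to be expected counts per gene symbol, the estimates RSEM gives, held by the authors as whole numbers: all values were whole, so rounding left them as they were. The table has 19396 rows, of which 1 names no gene, holds 0 counts and was left out. Of the 19395 genes, 3438 had 0 counts in all libraries. The columns of other samples numbered 0.

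Library totals were 18154839 to 18406885 counts, so 1 CPM equals about 18 counts, and differences of a few counts are within sampling noise. Intervals and floors cover counting error only, because counts were summed over the libraries of a group and the spread between libraries was left out. PCR copies are not independent molecules, so the intervals may be too narrow even for counting error. Without a stated strand setting, reads of genes that overlap on opposite strands cannot be told apart, and reads shared by paralogs such as AKR1C1, AKR1C2 and AKR1C3 or HSPA1A and HSPA1B were divided by the authors' estimation.

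Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group (minimum count 10), which left 12758 genes and set 6637 aside. Library sizes were scaled with TMM factors, which ranged from 0.988 to 1.01. The main comparison was edgeR's robust quasi-likelihood fit and F test of oeTNFRSF12A against oeControl, with group as the only term and Benjamini-Hochberg adjustment; a gene was called at an adjusted p under 0.05. CPM values use the TMM-scaled library sizes, and means are given with the SD over 3 libraries. For genes with few control counts, a ratio of summed counts scaled by library size is given with an exact (Clopper-Pearson) 95% interval, and a gene with 0 counts in a group was set to a floor of 3 counts over that group.

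Before the data were examined, 35 gene lists were written down, along with the tests, the alternatives and the rule for naming genes. Of 941 distinct members, 807 (85.8%) could be tested; symbols that had been replaced were matched through a table of older names. Lists with at least 5 tested members, 32 in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with the correlation preset at 0.01, adjusted over the 32 lists. Each member count is given over all tested genes and adjusted over the list alone. None of the 8 calls held with an estimated correlation. For the NF-kB (-0.0005), p53 (-0.037) and cholesterol (0.0072) lists that estimate was below the preset, so correlation between members did not end these calls. With an estimated correlation, camera also takes its degrees of freedom from the few residuals of the libraries in place of the many genes. This raises p at any correlation, so a call lost there does not by itself show correlation between members. The naming rule took TNFRSF12A, then the 8 largest rises and 8 largest falls among called genes with a mean of at least 50 counts and no overlap of the groups' CPM, then the 3 members of each list with the lowest p. Some genes that the rule names are not reported here. Genes outside the rule are identified as chosen after their values were seen. Overlaps with other genes were looked up for TNFRSF12A and for the 16 genes with the largest changes. Gene positions come from GENCODE release 29 on GRCh38; whether the authors used that release is not given in the sources used here.

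Replicates were compared before they were averaged. Chi-square statistics over 11453 genes with enough counts were 1.65 to 3.57 per gene within groups and 19.3 to 21.7 between groups, so no pair agreed within sampling noise and all 6 libraries were counted. The largest values within a group came from the pairs with oeTNFRSF12A replicate 3.

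The fitting and list tests were tested on simulated counts for the same 12758 genes and library sizes, with each gene drawn independently. The 1 list changed by 1.25-fold was called and 0 of 31 unchanged lists were. Correlation between list members was not simulated, so its effect on the list test is not covered. Of 50 genes changed by 1.25-fold 37 were recovered, of 50 changed by 1.5-fold 45, of 50 changed by 2-fold 48 and of 50 changed by 4-fold 50, with 17 false calls, and 1 call when nothing was changed. Far fewer genes were changed in the simulation than were called in the data. The adjustment and the scaling therefore met a different setting, and these rates need not hold for the data. Alternatives were DESeq2 size factors, upper-quartile factors or library totals alone, no filter or a stricter one, DESeq2 1.42.0 and limma-voom in place of edgeR, a replicate block, no robust estimation, TNFRSF12A left out of the totals, a stricter threshold, a minimum fold of 1.5, each library left out in turn, and for the lists an estimated correlation, fry and cameraPR. After the data were seen, a fit with trends on GC content and transcript length removed from each library was added, for which 97.6% of the tested genes had both values, along with camera at prior counts of 0.5 and 5. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.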

Results

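Polyadenylated RNA was sequenced from 6 libraries of human cells labelled as DLD-1, an established colorectal adenocarcinoma line of epithelial origin. The design asked how overexpression of TNFRSF12A alters the transcriptome of colorectal cancer cells, by comparing 3 libraries labelled oeTNFRSF12A with 3 labelled oeControl. TNFRSF12A, also called Fn14, is the surface receptor for the cytokine TWEAK and recruits TRAF adaptors to activate NF-kB. The oeTNFRSF12A cells had been given doxycycline at 0.1 µg/mL for 48 h, and the labels describe the oeControl cells as untreated and of WT genotype, so overexpression and exposure to doxycycline changed together. Whether the control cells carry an expression construct is not given in the labels, and its presence may differ between the groups too. Library totals ranged from 18154839 to 18406885 counts, and 14577 to 14788 genes had at least 1 count in a library. Mitochondrially encoded transcripts took 5.89% to 6.21% of the counts. The first principal component held 66.8% of the variance and placed the 3 libraries of each group on opposite sides. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

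TNFRSF12A transcript was 3.00-fold higher in the oeTNFRSF12A libraries. The controls held 404, 365 and 423 counts of the gene and the oeTNFRSF12A libraries 1203, 1133 and 1305, equal to 21.97 ± 1.60 and 65.9 ± 4.29 CPM, the count scaled by library size (mean ± SD, n = 3 per group). The log2 fold change was 1.59 (SE 0.06), with an adjusted p of 4.17e-16 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The gene (ENSG00000006327.13) lies on the plus strand of chromosome 16 from 3018445 to 3022383 (GRCh38, GENCODE release 29). Its 7 annotated transcripts have at most 4 exons, and 40 bp of exon are shared with CLDN6 on the opposite strand.

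Around this gene, 5402 of 12758 tested genes (42.3%) differed between the groups at an adjusted p under 0.05, 2709 higher and 2693 lower in the oeTNFRSF12A libraries. Most differences were small. The median fold of the changed genes was 1.19, 4675 of them changed by less than 1.5-fold, and 234 changed by at least 2-fold, 70 upward and 164 downward. The CPM ranges of the groups did not overlap for 6550 tested genes, 51.3% against the 10% that chance gives for 3 against 3 libraries. Replicates were close, with a biological coefficient of variation of 2.83%. When edgeR tested against a minimum fold of 1.5 in place of no change, 217 genes passed, 75 higher and 142 lower.

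**Figure D1:**
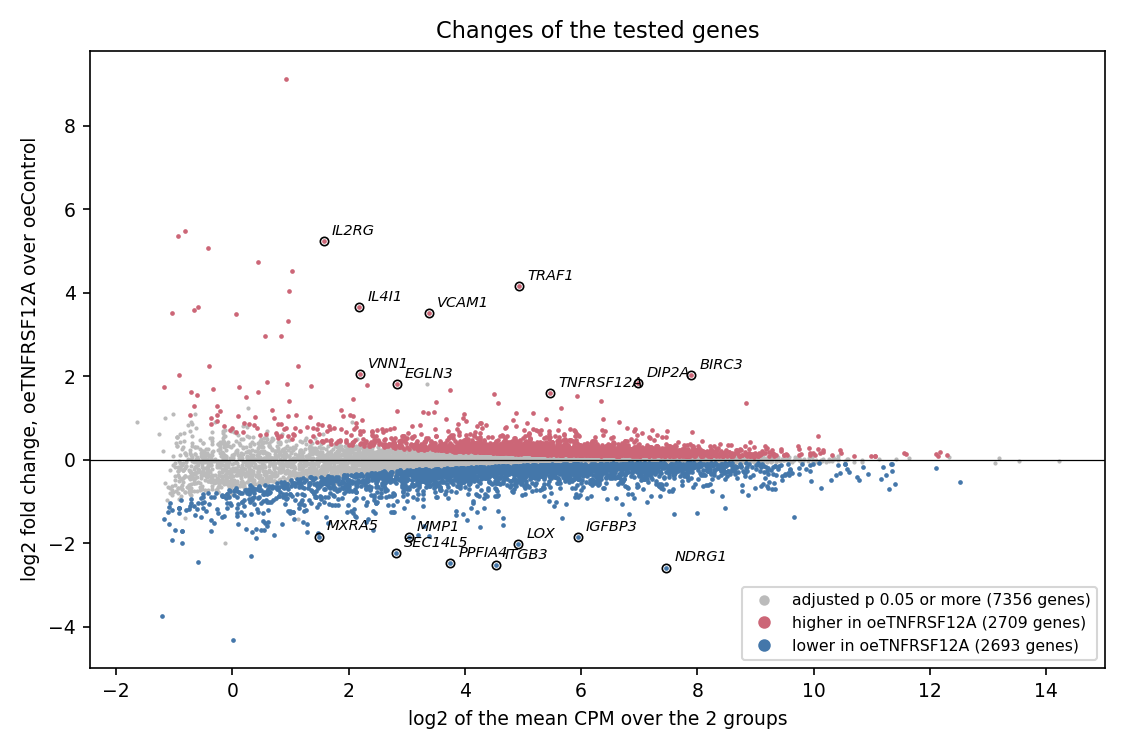
Log2 fold change of each tested gene (oeTNFRSF12A over oeControl) against the log2 of its mean CPM over both groups, 3 libraries per group. Red points mark the 2709 genes higher and blue points the 2693 genes lower at an adjusted p under 0.05, grey points the other tested genes, and circles the named genes with the largest changes.

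IL2RG, the common gamma chain of several interleukin receptors, went from 2 to 3 counts per control library to 99 to 120 counts, a ratio of 39.3 with a 95% counting interval of 19.7 to 91.8. Of its 2760 bp of exon, 1403 are shared with an overlapping gene model on the same strand, AL590764.2, so reads of these may be split with error. TRAF1, an adaptor of TNF receptors, rose from 3.21 ± 0.49 to 57.5 ± 2.86 CPM (log2 fold change 4.16, SE 0.09), and VCAM1, an adhesion molecule that binds leukocyte integrins, from 1.68 ± 0.33 to 19.2 ± 1.14 CPM (3.51, SE 0.12). BIRC3, encoding the ubiquitin ligase cIAP2, was already abundant in the controls and rose from 94.4 ± 4.31 to 381 ± 22.2 CPM (2.01, SE 0.04). IL4I1, a secreted amino acid oxidase, had a log2 fold change of 3.65, but its exons share 336 bp with NUP62 and 75 bp with ATF5, so its reads are uncertain in the same way. VNN1 (2.04), DIP2A (1.83) and EGLN3 (1.80), a prolyl hydroxylase that marks HIF for degradation, completed the 8 largest rises by the naming rule, and the adjusted p of these 8 genes was at most 3.62e-10 (edgeR quasi-likelihood test, Benjamini-Hochberg).

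NDRG1, a hypoxia-induced stress gene, went from 303 ± 10.1 to 50.3 ± 0.92 CPM (log2 fold change -2.59, SE 0.04). ITGB3, the integrin beta-3 chain, went from 39.8 ± 4.97 to 6.86 ± 0.39 CPM (-2.53, SE 0.10), and 2266 bp of its exons are shared with an overlapping readthrough model, AC068234.1. LOX, which cross-links collagen and shares 138 bp of exon with SRFBP1 on the opposite strand, fell from 48.6 ± 2.53 to 11.9 ± 0.75 CPM (-2.03), and IGFBP3, a carrier of insulin-like growth factors, from 96.2 ± 4.63 to 26.5 ± 1.78 CPM (-1.86). PPFIA4 (-2.49), SEC14L5 (-2.24), the collagenase gene MMP1 (-1.86) and the matrix gene MXRA5 (-1.85) were the others of the 8. Their largest adjusted p was 2.20e-08 (edgeR quasi-likelihood test, Benjamini-Hochberg).

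**Figure D2:**
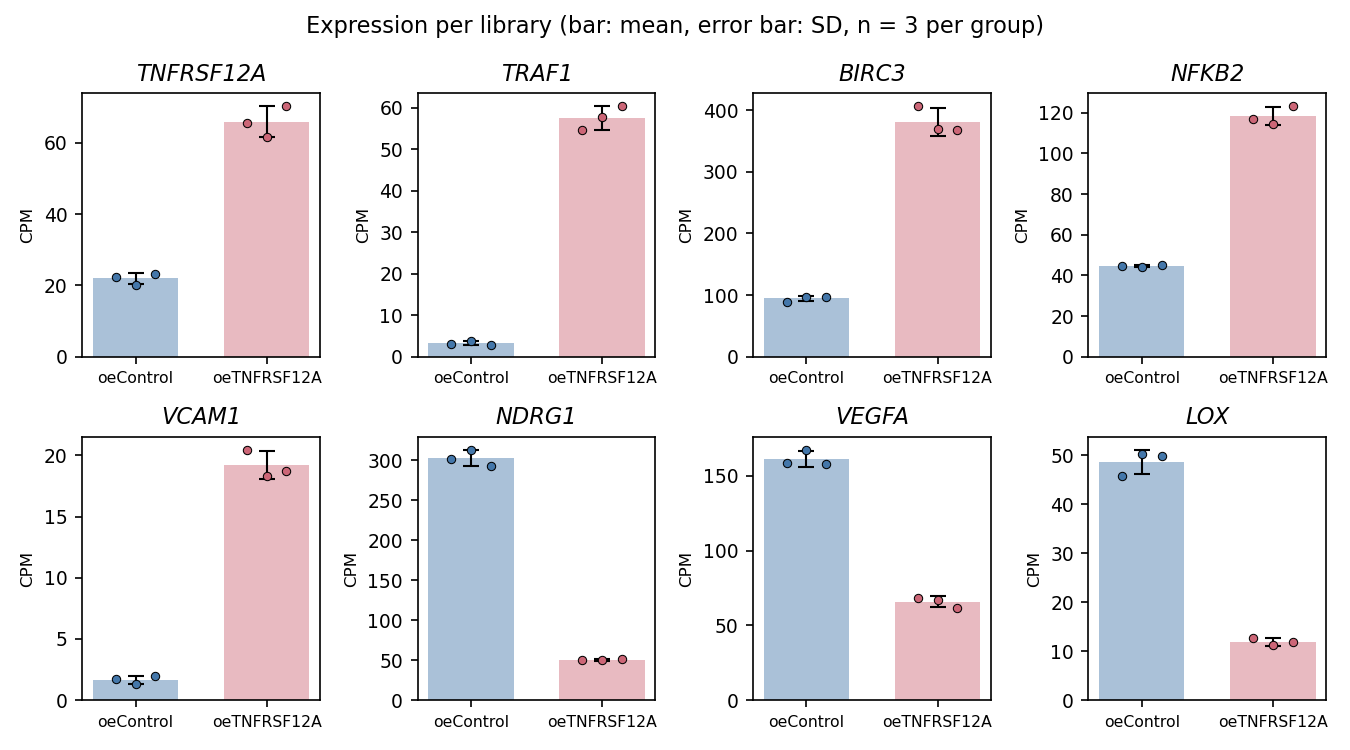
CPM of 8 genes in each library; bars give the group mean, error bars the SD and points the 3 libraries of each group. TRAF1, BIRC3, NFKB2 and VCAM1 rose with TNFRSF12A, and NDRG1, VEGFA and LOX fell, with no overlap between the groups.

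NF-kB target genes rose as a list. Of 24 tested members 13 rose, 4 fell and 7 did not pass (14 and 4 adjusted over the list alone), and camera gave an adjusted p of 4.73e-04 upward, against an adjusted p of 0.160 with an estimated correlation. NFKB2, the p100 precursor of the non-canonical pathway, rose from 44.6 ± 0.59 to 118 ± 4.53 CPM (log2 fold change 1.41). Its partner RELB (0.87), the NF-kB inhibitors NFKBIA (0.73), NFKBIE (1.09) and TNFAIP3 (1.10), and BIRC2 (0.71) also rose; these members, like others named below beside the 3 with the lowest p per list, were chosen after their values were seen. IER3 (-0.43), BCL3 (-0.40), TNFAIP2 (-0.29) and BCL2L1 (-0.27) fell, and ICAM1, a classical NF-kB target, stood at -0.01 without passing. TNFRSF9, the receptor 4-1BB, had 1 to 5 counts per control library and 70 to 74 per oeTNFRSF12A library, a ratio of 23.6 (95% counting interval 12.2 to 52.3).

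Genes of glycolysis and of the response to hypoxia fell together. Of 31 tested members 27 fell and 2 rose (28 and 2 adjusted over the list alone), with a median log2 fold change of -0.49. The camera adjusted p was 6.08e-12, and the adjusted p was 0.123 with an estimated correlation. Beside NDRG1, VEGFA, the main angiogenic growth factor, went from 161 ± 5.40 to 65.7 ± 3.65 CPM (-1.30), and ENO2, a glycolytic enolase, from 141 ± 0.70 to 67.0 ± 1.05 CPM (-1.07). The glucose transporter SLC2A1 (-0.63), hexokinase HK2 (-0.81), LDHA (-0.49) and GAPDH (-0.37) fell as well. EGLN3, itself a hypoxia-inducible gene, went the other way (1.80), as did PKM by a small amount (0.09).

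Antioxidant genes of the NRF2 programme were lower. Of 27 tested members 17 fell and 2 rose (18 and 2 adjusted over the list alone), with a camera adjusted p of 3.87e-05 and an adjusted p of 0.287 with an estimated correlation. The quinone reductase NQO1 went from 355 ± 8.17 to 238 ± 7.71 CPM (log2 fold change -0.58), the haem oxygenase HMOX1 from 56.6 ± 3.36 to 32.5 ± 0.49 CPM (-0.80), and the transporter ABCC3 changed by -0.46. The 2 that rose were PGD (0.18), an enzyme of the pentose phosphate pathway, and KEAP1 (0.30), the negative regulator of NRF2.

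Most cell cycle genes rose, by small amounts. In the S phase list 29 of 34 rose and 0 fell (31 adjusted over the list alone), with a median log2 fold change of 0.22. The G2 and M phase list had 32 of 33 higher and 0 lower (32 adjusted over the list alone), with a median of 0.28. PCNA, the replication clamp, rose from 176 ± 0.23 to 220 ± 3.68 CPM (0.32), CLSPN by 0.39 and TYMS by 0.28. MKI67, the proliferation marker, rose from 451 ± 15.9 to 555 ± 6.23 CPM (0.30), ECT2 by 0.36 and CENPF by 0.28. Camera gave adjusted p-values of 3.48e-10 and 5.68e-12 for these lists, and adjusted p was 0.204 and 0.222 with an estimated correlation.

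Ribosome biogenesis and cholesterol genes moved the same way. Of 31 ribosome biogenesis genes 24 rose and 1, PPAN, fell by 0.20 on the log2 scale (26 and 1 adjusted over the list alone); RRS1 changed by 0.50, RRP12 by 0.40 and the helicase DDX21 by 0.31. The camera adjusted p was 2.54e-06, and adjusted p was 0.481 with an estimated correlation. Of 25 genes of cholesterol synthesis and uptake 16 rose and 0 fell (17 adjusted over the list alone), among them the early enzymes FDPS (0.35), HMGCS1 (0.31) and IDI1 (0.27). Camera gave an adjusted p of 3.72e-04, against an adjusted p of 0.160 with an estimated correlation. The cytosolic ribosomal proteins themselves had 1 of 40 higher and 1 lower (0 adjusted over the list alone), with a list median of -0.01. The call on the RPLP1 log2 fold change (0.11) was lost with upper-quartile factors (0.10), and that on the RPL3 log2 fold change (-0.08) with library totals alone (-0.06); RPLP1 was also lost without any library but oeTNFRSF12A replicate 1, lowest without oeTNFRSF12A replicate 3 (0.05), and RPL3 without oeControl replicate 1 (-0.06) or 3 (-0.08) or oeTNFRSF12A replicate 1 (-0.07) or 2 (-0.07).

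Among p53 target genes 10 of 23 rose and 1, GDF15, fell (10 and 1 adjusted over the list alone). The death receptor genes FAS (0.76) and TNFRSF10B (0.29) and the nuclease AEN (0.59) led the list, while CDKN1A, the classical p53-induced cell cycle inhibitor, rose by 0.17. Camera gave an adjusted p of 0.0246, against an adjusted p of 0.222 with an estimated correlation, and fitting the replicate number as a block ended the call (adjusted p = 0.0594). FAS and TNFRSF10B also stand in the TNF receptor list. Of 28 apoptosis machinery genes 9 rose and 2 fell (9 and 2 adjusted over the list alone), led by BMF (-0.35), CYCS (0.17) and BID (0.30), with no call for the list (camera adjusted p = 0.204).

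**Figure D3:**
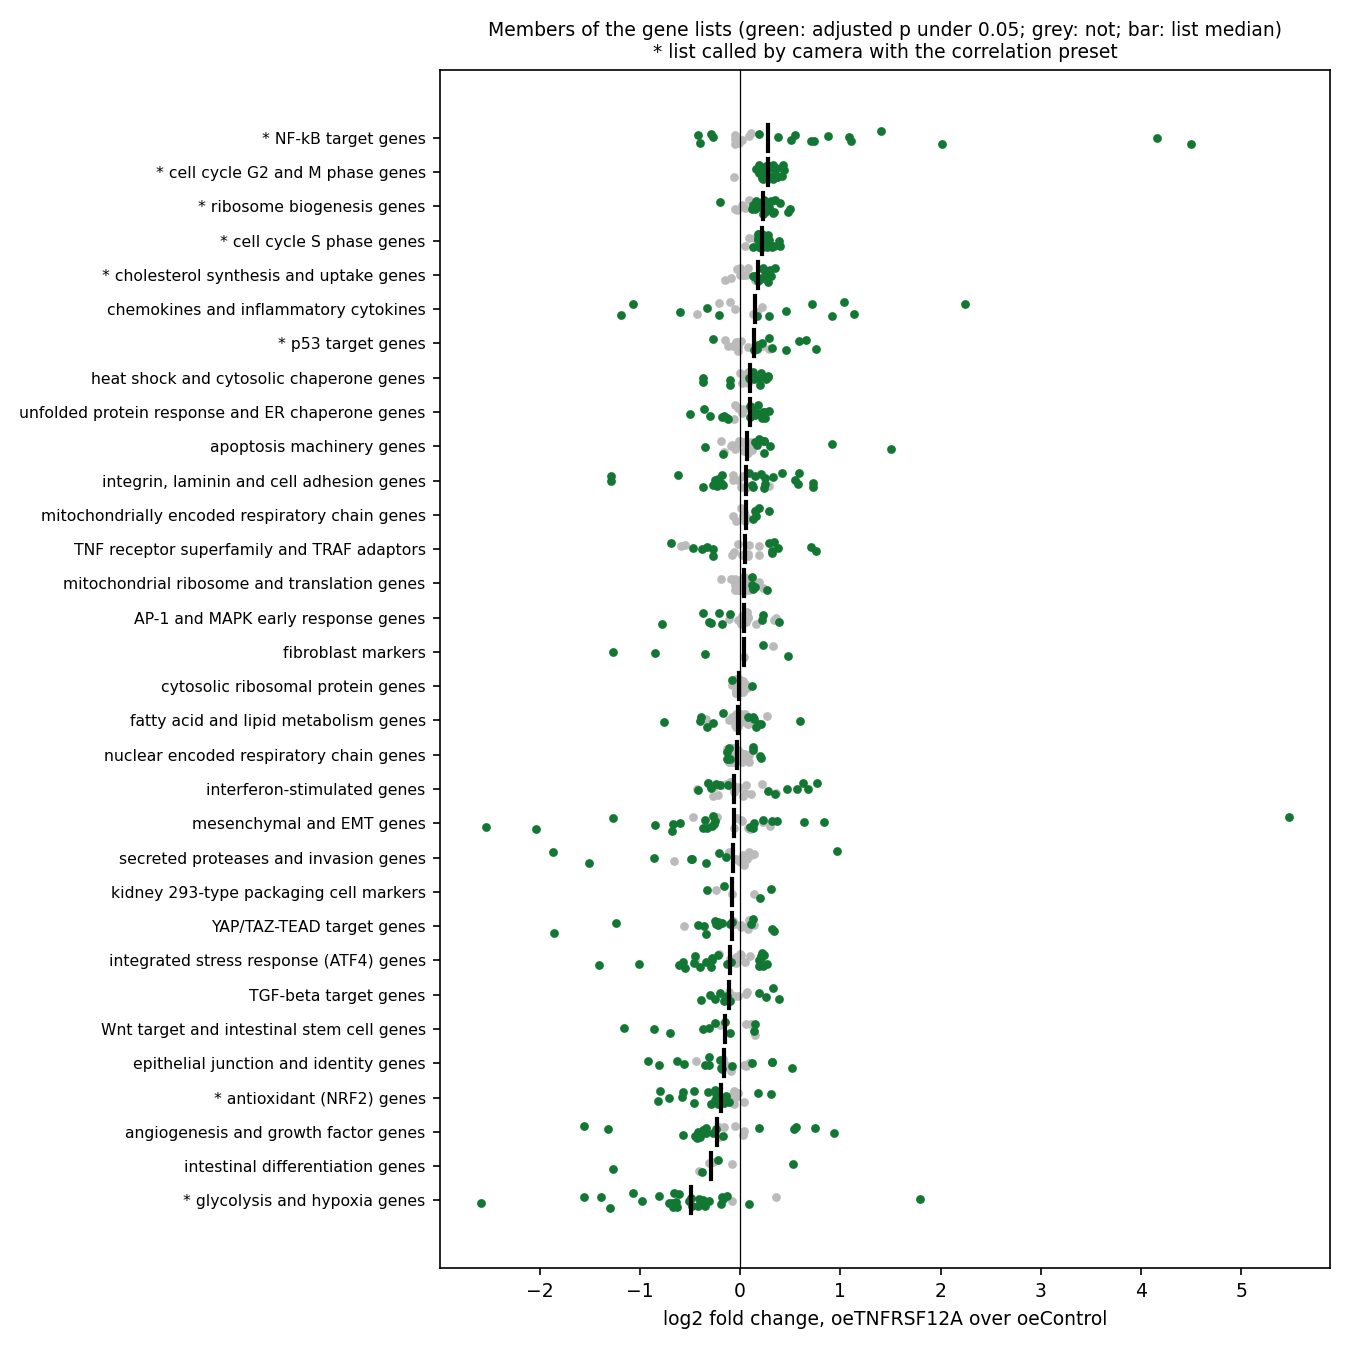
Log2 fold change (oeTNFRSF12A over oeControl) of every tested member of the 32 gene lists with at least 5 tested genes, ordered by list median (black bar). Green points passed the test for single genes and grey points did not; an asterisk marks the 8 lists called by camera, 6 upward and 2 downward.

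Inflammatory ligands and receptors split in direction. Of 20 tested chemokine and cytokine genes 8 rose and 5 fell (8 and 6 adjusted over the list alone). CCL2, which attracts monocytes, rose from 34.1 ± 2.14 to 64.5 ± 1.67 CPM (log2 fold change 0.92) and IL32 by 0.72, while LIF, a cytokine of the IL6 family, fell by 0.60 on the log2 scale. In the list of TNF receptors and TRAF adaptors 7 of 24 rose and 6 fell (7 and 7 adjusted over the list alone); FAS, TNFRSF21 (0.31) and TNFRSF10B rose, and TNFSF12, which encodes the ligand TWEAK, changed by -0.47. Of 35 interferon-stimulated genes 7 rose and 6 fell (7 and 6 adjusted over the list alone), with rises of IFIH1 (0.77) and TAP1 (0.62) and falls of IFIT1 (-0.42) and IRF9 (-0.32). The early response genes of AP-1 and MAPK signalling had 3 of 24 higher and 7 lower (3 and 7 adjusted over the list alone), with EGR1 at -0.78, DUSP4 at -0.37 and DUSP10 at 0.39. None of these 4 lists was called (camera adjusted p = 0.532, 0.532, 0.882 and 0.947). The median and the mean differed in sign for the AP-1 list (0.04 and -0.01, camera direction up) and the interferon list (-0.06 and 0.02, camera direction down).

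Adhesion and matrix genes changed widely in both directions. Of 35 integrin, laminin and adhesion genes 15 rose and 12 fell (17 and 13 adjusted over the list alone). ITGB4, the hemidesmosome integrin, went from 274 ± 8.52 to 112 ± 1.94 CPM (log2 fold change -1.29) and ITGB5 changed by -0.62, whereas the collagen receptor chain ITGA2 rose by 0.73. In the mesenchymal list 9 of 33 rose and 14 fell (10 and 14 adjusted over the list alone). LOX, ITGB3 and LOXL2 (-0.68) led the falls and TNC (0.64) and INHBA (0.84) were among the rises. MMP9, a gelatinase, had 0 to 1 counts per control library and 16 to 28 per oeTNFRSF12A library, a ratio of 60.9 whose 95% counting interval reached from 10.5 to 2445. Of 20 secreted protease genes 1, MMP7, rose and 8 fell (1 and 8 adjusted over the list alone), MMP1, ADAMTS1 (-0.86) and CTSD (-0.48) with the lowest p. Targets of YAP and TEAD had 4 of 25 higher and 12 lower (6 and 13 adjusted over the list alone), with IGFBP3, NT5E (-0.42) and MYOF (-0.36) leading, although CCN2, a widely used target, rose by 0.34. TGF-beta targets had 4 of 18 higher and 8 lower (4 and 8 adjusted over the list alone), led by LTBP3 (-0.39), TGFB1 (-0.30) and ID3 (0.39). Camera called none of these 5 lists (adjusted p = 0.741, 0.204, 0.109, 0.103 and 0.465).

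Camera called no growth factor or stress list. Of 24 angiogenesis and growth factor genes 5 rose and 13 fell (5 and 14 adjusted over the list alone; camera adjusted p = 0.0542); ANGPTL4, a hypoxia and lipid responsive factor, changed by -1.56, and the Notch ligand JAG1 (0.75) and NRG1 (0.54), a ligand of ERBB receptors, rose. Integrated stress response genes had 8 of 33 higher and 15 lower (8 and 15 adjusted over the list alone; camera adjusted p = 0.103), with DDIT4 (-1.41), STC2 (-1.01) and the amino acid transporter SLC7A5 (-0.61) in front. Chaperones of the endoplasmic reticulum had 11 of 25 higher and 7 lower (11 and 7 adjusted over the list alone; camera adjusted p = 0.532), with HSP90B1 at 0.23, DNAJB11 at 0.28 and EDEM2 at -0.50. Cytosolic chaperones had 11 of 20 higher and 4 lower (12 and 4 adjusted over the list alone; camera adjusted p = 0.098), with HSPE1 at 0.28, AHSA1 at 0.28 and BAG3 at -0.37. The angiogenesis list gained a call with library totals alone and without oeControl replicate 2 or oeTNFRSF12A replicate 1, and the cytosolic chaperones without oeTNFRSF12A replicate 1 (camera adjusted p of 0.0374 to 0.0488 in these fits).

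Camera called neither the fatty acid and lipid list nor a mitochondrial list. Of 29 fatty acid and lipid genes 7 rose and 6 fell (7 and 6 adjusted over the list alone; camera adjusted p = 0.892); the lipid droplet gene PLIN2 changed by -0.76, SCD by -0.27 and DGAT2 by 0.59. Of the 13 mitochondrially encoded genes 5 rose and 0 fell (5 adjusted over the list alone; camera adjusted p = 0.142), MT-ND2 by 0.19, MT-ND3 by 0.16 and MT-ATP8 by 0.29. Nuclear respiratory chain genes had 4 of 39 higher and 4 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.532), with UQCRFS1 at 0.20 and ATP5F1A at -0.13. Mitochondrial ribosome and translation genes had 5 of 36 higher and 0 lower (3 adjusted over the list alone; camera adjusted p = 0.204), with GFM1 at 0.27 and TFAM at 0.15. The camera adjusted p of the cytosolic ribosomal proteins was 0.721.

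Epithelial junction genes had 4 of 24 tested members higher and 11 lower (4 and 14 adjusted over the list alone; camera adjusted p = 0.213). CDH1, the epithelial cadherin, went from 17.05 ± 1.14 to 9.0 ± 0.42 CPM (log2 fold change -0.92), while the tight junction gene CLDN1 (0.32) rose. KRT8 (171 ± 1.89 and 162 ± 4.20 CPM in control and oeTNFRSF12A libraries) and KRT18 were expressed in both groups, and of the list's 31 members 21 reached 1 CPM in all 6 libraries and 9 stayed under 1 CPM in all of them. EPCAM, the common surface marker of epithelial cells, had 13 counts over all 6 libraries together, the keratin gene KRT19 had 14, the intestinal transcription factor CDX2 had 4 and CEACAM5 had 0. Of 35 intestinal differentiation genes 7 reached 1 CPM in all 6 libraries and 27 stayed under 1 CPM in all of them; 8 could be tested, of which 1 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.204), with the mucin MUC1 at -1.27, KLF5 at -0.22 and KLF4 at 0.53 on the log2 scale. The call on the KLF5 log2 fold change was lost in DESeq2 (-0.22) and without oeTNFRSF12A replicate 2 (-0.21) or 3 (-0.16) or oeControl replicate 2 (-0.19) or 3 (-0.20). Of 15 tested Wnt target and stem cell genes 2 rose and 8 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.150), with CD24 at -0.70, BMP4 at -0.86 and AXIN2, a direct Wnt target, at -0.37. The Wnt effector LEF1 had 0 counts, which allows up to 3 counts over the 6 libraries, and the stem cell receptor LGR5 had 2.

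Mesenchymal and kidney-lineage transcripts were present in the same libraries. VIM, the mesenchymal intermediate filament, ranked 10 among all genes by mean CPM, at 4230 ± 95.5 CPM in the controls and 4620 ± 107 CPM in the oeTNFRSF12A libraries. COL6A3 stood at 6966 ± 236 and 4760 ± 74.7 CPM, and FN1, fibronectin, at 1500 ± 28.5 and 1159 ± 49.2 CPM. The transcription factor PAX2 (46.3 ± 2.85 and 36.7 ± 0.96 CPM), which acts in the developing kidney, was expressed in both groups. COL6A3 and FN1 were chosen after their values were seen.

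**Figure D4:**
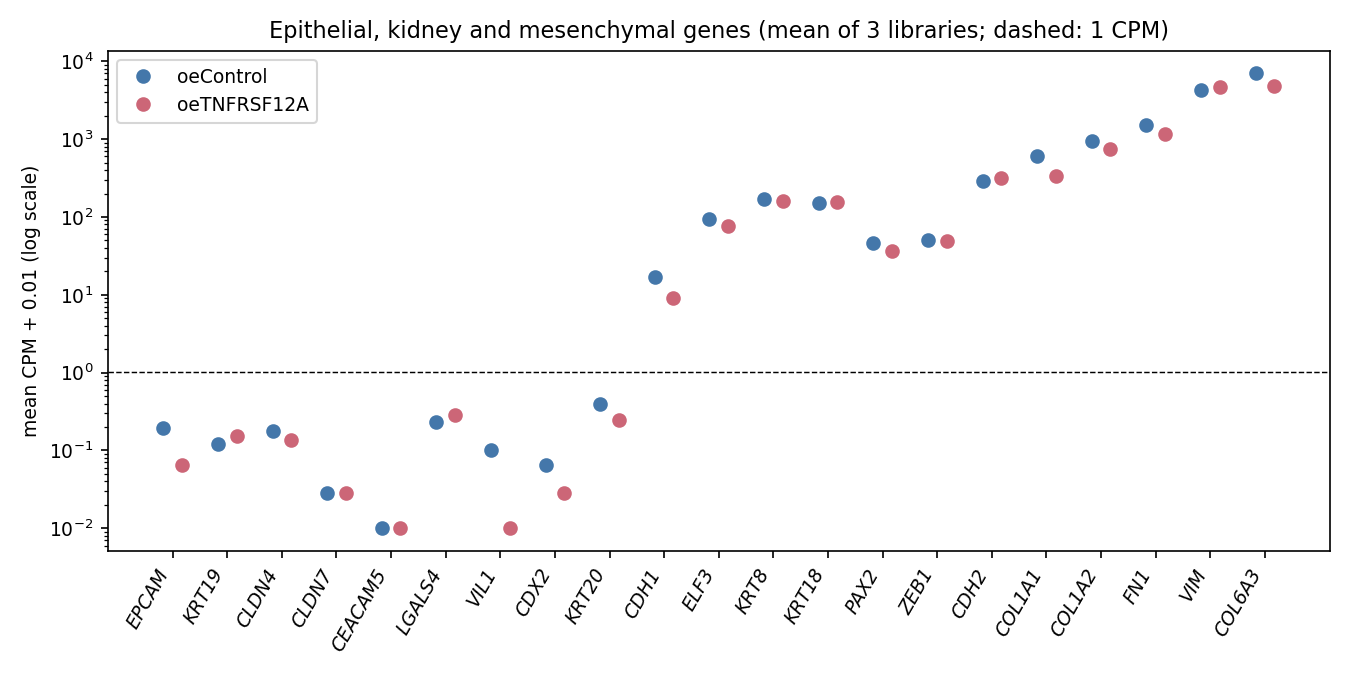
Mean CPM plus 0.01 (log axis) of epithelial, kidney and mesenchymal genes in the 3 oeControl (blue) and 3 oeTNFRSF12A (red) libraries; the dashed line marks 1 CPM. EPCAM, KRT19, CDX2 and CEACAM5 lie under the line in both groups, and VIM, FN1 and COL6A3 lie over 1000 CPM.

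Marker lists of cells that a DLD-1 culture should lack gave the following. Of 12 fibroblast markers 7 could be tested, 2 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.644), and the list's median (0.04) and mean (-0.20, camera direction down) differed in sign. The collagen genes COL1A1 (599 ± 31.9 and 333 ± 13.8 CPM, log2 fold change -0.85) and COL1A2 (-0.35) fell and COL3A1 (0.23) rose; these 3 genes also stand in the mesenchymal list. Of 12 kidney packaging-cell markers 7 could be tested, 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.761), PAX2 by -0.33, CDH6 by 0.31 and INA by 0.20. The call on the INA log2 fold change was lost in DESeq2 (0.20) and without oeControl replicate 2 (0.20) or 3 (0.16) or oeTNFRSF12A replicate 1 (0.15) or 3 (0.19). The call on the CDH6 log2 fold change was lost without oeControl replicate 1 (0.32) or oeTNFRSF12A replicate 1 (0.28). Leukocyte markers were near the floor, with 2 of 15 tested; ITGAM, an integrin of myeloid cells, rose from 0.85 ± 0.12 to 2.99 ± 0.64 CPM (1.81), and CD14 stood at 1.46 ± 0.13 and 1.59 ± 0.29 CPM. Of 10 endothelial markers 2 were tested, ROBO4 (0.53 ± 0.17 and 1.19 ± 0.49 CPM) and PECAM1 (1.38 ± 0.24 and 0.74 ± 0.22 CPM), with calls in opposite directions. The call on the ROBO4 log2 fold change (1.15) was lost without oeControl replicate 1 (0.97) or oeTNFRSF12A replicate 3 (0.79). That on the PECAM1 log2 fold change (-0.89) was lost in DESeq2 (-0.90) and without oeControl replicate 1 (-0.80) or 3 (-0.83) or oeTNFRSF12A replicate 3 (-0.66). The list of RNA quality genes had 2 tested members, H2BC21 (1.60 ± 0.06 and 2.19 ± 0.15 CPM) and H2AC20 (0.77 ± 0.19 and 0.76 ± 0.33 CPM), neither of which passed, so it could not serve as a check of RNA quality.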

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

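The fit with GC and length trends removed and the prior counts of 0.5 and 5 for camera were chosen after the result was seen; the other alternatives were set before. TNFRSF12A stayed called in every alternative, with log2 fold changes of 1.53 to 1.63. The count of changed genes (5402) stayed between 3792 (adjusted p under 0.01) and 5773 (GC and length trends removed) in all alternatives but the minimum fold of 1.5, which passed 217 genes, 75 higher and 142 lower, because most changes are smaller than that. DESeq2 called 3926 genes, of which 3923 were among the calls of edgeR. Of the calls 50.1% were upward, against 56.5% without composition factors and 46.3% with upper-quartile factors. Leaving out 1 library in turn gave 4506 to 5298 changed genes and 244 to 260 changed at least 2-fold. Replicate numbers did not pair the libraries: same-numbered libraries correlated at -0.02, 0.02 and 0.03, and not every library correlated best with its own number. A replicate block gave 5396 changed genes, 2711 higher and 2685 lower, 237 at least 2-fold, a TNFRSF12A log2 fold change of 1.59 and 7 lists; beyond the p53 call it changed no call of a named gene or list. Of the 8 gene lists called, 0 held with an estimated correlation, where 6 lists had an unadjusted camera p under 0.05. For the NF-kB, p53 and cholesterol lists the estimate lay below the preset of 0.01, so a higher correlation did not end those calls. They were lost because this setting also uses the few residual degrees of freedom of the libraries. For the other called lists both changes act together, and their shares were not separated. Fry called 21 lists directionally and 31 in either direction, and cameraPR 14, adding the mesenchymal, protease, YAP and TEAD, Wnt target, integrated stress response and fibroblast lists; the cause was not tested. Prior counts of 0.5 and 5 kept the same 8 lists. The other settings, left-out libraries included, called 8 to 10 lists and kept all 8. Over 109 other named genes, 1817 of 1851 alternative values kept direction and call; 9 genes changed a call (KLF5, MRPL3, RPLP1, RPL3, RPS7, ROBO4, PECAM1, CDH6 and INA) and 0 reversed. The alternatives planned only for normalized values (a pseudocount in the gene test and no filter on low values of that kind) were not run, since the values are counts. At this depth, changes of genes with few counts had wide intervals.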

Other observations

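The tests of GC content and length, copy number, doxycycline, culture density and cell identity were chosen after the result was seen, as were the genes named here; the tests of other splits of the libraries and of neighbouring genes were set before their own results were seen. Some genes outside the lists were near absent in 1 group and had more counts in the other. TMEM265, a small transmembrane protein gene, had 0 counts in the control libraries and 64 to 75 in each oeTNFRSF12A library, at least 55.4-fold higher by the lower 95% counting limit (68.8-fold against a floor of 3 counts over the group). PLEK, a protein kinase C substrate of blood cells, went from 0 to 1 counts per control library to 15 to 22 (ratio 56.0, 95% counting interval 9.66 to 2251). In the other direction, ISM2 had 31 to 42 counts per control library and 1 to 3 per oeTNFRSF12A library (ratio 0.0468, interval 0.0149 to 0.113), and PRTN3, a serine protease of neutrophils, 11 to 17 and 0 to 2 (ratio 0.067, interval 0.0133 to 0.209).

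PADI1, PADI2 and PADI3, which encode enzymes that convert arginine to citrulline in proteins, were lower. PADI2 went from 1177 ± 7.61 to 452 ± 14.4 CPM (log2 fold change -1.38), PADI3 from 492 ± 10.5 to 219 ± 9.68 CPM (-1.17) and PADI1 from 7.45 ± 0.61 to 3.64 ± 0.55 CPM (-1.03; n = 3 per group). These genes lie side by side in the genome, and one hypothesis is that neighbouring genes share their changes more widely. Tested genes with a known position and a mean of at least 50 counts were put in genome order. Across 11176 pairs of neighbours among these genes, the log2 fold changes had a Spearman correlation of 0.0835. The largest value in 1000 shuffles of the gene order was 0.0290 (one-sided permutation p = 0.001, the smallest these can give). Genes are not independent replicates, and the correlation is small, so it may account for little of the fall in this cluster.

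A large share of tested genes, 5402 of 12758, changed by small amounts. With trends on GC content and transcript length removed from each library, 5773 genes were called, 5197 of them among the original calls, which argues against such a trend as the whole cause. Copy-number differences between the cell populations would place changed genes in shifted stretches, but 0.51% of them lay in windows of 25 neighbours with a median log2 change of at least 0.2 in size (window medians -0.33 to 0.18). The median absolute log2 change of the changed genes was itself 0.25, so shared shifts smaller than 0.2 would be missed. Doxycycline and TNFRSF12A cannot be told apart, because 0 control libraries were labelled as given doxycycline, and either, or the construct where the controls (labelled WT) lack it, may contribute. Among the 10 splits of the 6 libraries, 1 (the real one) reached the counts of 5402 changed, 2709 higher, 2693 lower and 234 at least 2-fold by edgeR. The highest other count was 0 for each (at most 282 genes at an unadjusted p under 0.05). For called lists 2 splits reached the real 8, with 9 as the highest other. Each split other than the real one called 2 to 9 lists by camera, 2 to 6 of them among the real 8, although it called 0 genes. The 10 splits are too few for a share under 0.05. Each split other than the real one also mixes libraries of both groups. The group difference then widens the spread within its groups, which lowers the gene calls, and part of it remains between them, which can yield list calls. Neither count is therefore a level that chance gives.

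Glycolysis and hypoxia genes fell, with a list median of -0.49 on the log2 scale. With GC and length trends removed the median was -0.50, which argues against such a trend. Control cultures that were denser or had grown longer, an action of TNFRSF12A and an action of doxycycline cannot be told apart, since the labels give no culture density and 0 control libraries were labelled as given doxycycline. The 67 genes of both cell cycle lists together had a median log2 fold change of 0.25, which was known before this test was chosen and decides nothing between them. EGLN3, which hypoxia induces, went the other way (1.80).

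Many colon epithelial genes were near the floor in all 6 libraries labelled DLD-1, while VIM ranked 10 by mean CPM. Colon epithelial cells mixed with a second cell type are argued against, because 0 of 7 transcripts abundant in such cells (EPCAM, KRT19, CLDN4, CLDN7, CEACAM5, LGALS4 and VIL1) reached 1 CPM in any library. A cell population other than the labelled line and a mesenchymal state of the labelled line cannot be told apart, because the values at hand would come from either. Of 35 intestinal differentiation genes 7 reached 1 CPM in all libraries, which restates the pattern, and all 4 of VIM, CDH2, ZEB1 and FN1 exceeded 10 CPM in every library. The pattern was in both groups and does not set them apart.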
